A study of Gallus gallus with 16 samples.

How the data were processed

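RNA sequencing was analysed from 16 cultures of LMH, a chicken hepatocellular carcinoma line established from a male Leghorn. The labels give each culture an inhibitor, PP1 or PP2, and an infection state, with or without infectious laryngotracheitis virus (ILTV), an alphaherpesvirus of chickens. This gives 4 groups of 4 libraries, named here PP1 uninfected, PP1 ILTV, PP2 uninfected and PP2 ILTV. The design text calls the 4 libraries of each group biological replicates. PP1 was used at 2 µM and PP2 at 20 µM, both in DMSO, so the compound and its dose changed together. A vehicle-only group was not analysed here, and the time after infection is not given in the sources used here.

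Per the labels, cDNA was amplified with the Smart-Seq2 protocol before libraries were made. Molecules were not tagged with identifiers in any step the labels describe, so reads are not independent molecules. Per the submitters' processing notes, Bowtie2 2.2.3, TopHat2 2.0.12 and Cufflinks 2.2.1 were used, with no role or order stated. The genome build and annotation are not given in the sources used here. The deposited values are FPKM, fragments scaled to the length of the feature and to the mapped fragments of the library, 1 value per feature and library. That unit was inferred from the values and the named tools, since the file headers carry a sample name only. Whether the libraries were also scaled to one another is not known here. An FPKM value divides by a feature length, and where that length is corrected for fragment size in each library, very short features can take values that are large and unstable between libraries.

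Each library lists the same 17188 features. Of these, 17108 carry chicken Ensembl gene identifiers, 79 are coding sequences of a viral reference record, and 1 is EGFP, which is listed at 0 in all 16 libraries. The viral record is known from general knowledge, not from the files, to be the reference genome of ILTV. Its coding sequences are called here by their order in the record, from 1 to 79. The files do not pair the chicken identifiers with gene names, and 0 of the 17108 matched the supplied reference table. The 36 gene lists fixed before the data were examined could therefore not be tested, and no chicken gene is named by symbol. The Src family members that the rule for named genes asked for could not be looked up either.

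Depth cannot be read from FPKM as a total. Relative depth was estimated from features with low values, where values are whole multiples of the value of 1 read. The most frequent ratio of each library to PP1 uninfected replicate 1 over 1895 low features was taken as the ratio of their read values. On this scale, relative depth ran from 0.763 in PP2 ILTV replicate 1 to 1.22 in PP2 uninfected replicate 2. Of 3327 low features, 912 gave whole reads in every library within a tolerance of 0.06 reads. Among them, 434 to 550 features per group averaged over 2 reads, and in these the variance between replicates was 1.45 to 1.62 times the mean, so counting error alone understates the spread at low values. The estimate was tested on simulated libraries of 10541 features before use.

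Values were transformed to log2(FPKM + 1), and fold changes are on this scale, which understates changes of low features. Features above 1 FPKM in at least 4 libraries were kept, 10614 in all, made of 10541 host and 73 viral features. Because the files hold FPKM and not counts, the design fixed for normalized values was used: limma 3.58.1 in R 4.3.3, with 4 group means over all 16 libraries and eBayes with trend and robust settings. The Benjamini-Hochberg adjustment ran over all 10614 features, and calls are at an adjusted p under 0.05. No further scaling was applied. Median host deviations of single libraries lay between -0.0368 and 0.0327 on the log2 scale.

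The fit was tested on simulated values with 200 changed features out of 10541. For infection with PP1, 40% of features changed by 0.25 log2 and 96% of those changed by 1 log2 were recovered. For the difference between inhibitors in the response to infection, 24% and 84% were recovered at these sizes. False calls ran from 4 of 140 calls, for this difference, to 13 of 176, for PP2 against PP1 in infected cells. The simulation changed far fewer features than the 51.3% and 57.4% called for infection with PP1 and PP2, which makes the adjusted threshold stricter. It also drew each feature with the same SD in all 4 groups. In the real groups the median coefficient of variation of host features of at least 100 FPKM ran from 3.27% to 5.54%. The rates of recovery and of false calls therefore hold for the simulated setting only.

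The rule for named genes asked for gene symbols, which the files do not give. Up to 2 identifiers that rose and 2 that fell per comparison are printed instead, in the order of that rule. They had an adjusted p under 0.05, a mean of at least 5 FPKM in the higher group and no overlap between groups. The condition on overlap was not applied to the difference of responses. All libraries of the comparison had to be above 0, a condition added after the missing symbols had been seen. For the viral coding sequences, the difference between inhibitors was also tested after centring each infected library on its own viral median, by limma over the 73 sequences. Single values per library were compared by exact permutation tests, two-sided. Whole-library trends and neighbouring sequences were tested with 100000 permutations.

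The alternatives were quantile normalization, upper-quartile scaling, no filter, a stricter filter of 10 FPKM, a pseudocount of 0.1, only the groups compared, the replicate number as a block, a fold threshold of 1 on the log2 scale, and leaving out each library. Centring on the host median, a weight per library, features above 0 in every library and leaving out groups of libraries or features were added after seeing the data. Python 3.11.15 with NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9 was used for read values and plots.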

Results

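Transcript levels were measured in LMH chicken hepatoma cells treated with PP1 at 2 µM or PP2 at 20 µM, with or without ILTV infection. PP1 and PP2 are pyrazolopyrimidine inhibitors of Src family kinases that differ in the substituent of a phenyl ring, a methyl group in PP1 and a chlorine in PP2. The series title frames the work as a search for the host regulation behind the suppression of ILTV by these compounds. The 16 libraries fell into 4 groups of 4, and each reported 12712 to 12982 features above 0 FPKM. Relative depth lay between 0.763 and 1.22 of that of PP1 uninfected replicate 1. It was 0.763 to 0.862 in the PP2 ILTV libraries and at least 0.895 in every other library. Comparisons with PP2 ILTV therefore also set shallower against deeper libraries. Host values of libraries of the same group correlated at 0.986 to 0.994 across features, and those of different groups at 0.960 to 0.985. The median coefficient of variation of host features of at least 100 FPKM was 3.27% in PP1 uninfected, 4.34% in PP1 ILTV, 3.55% in PP2 uninfected and 5.54% in PP2 ILTV cells.

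Viral transcripts were abundant in every library labelled infected. The FPKM of the 79 viral coding sequences summed to 118749 ± 8634 (SD, n = 4) in PP1 ILTV cells and to 238777 ± 7364 (SD, n = 4) in PP2 ILTV cells. The same sum was 48.8 ± 1.83 (SD, n = 4) in PP1 uninfected and 54.4 ± 20.9 (SD, n = 4) in PP2 uninfected cells, where replicate 4 stood at 85.2, of which coding sequence 59 gave 46.9. Coding sequences 13 and 14 stood highest, at 30223 ± 487 and 24849 ± 762 FPKM (SD, n = 4) with PP1, and at 57483 ± 1097 and 46585 ± 1536 FPKM (SD, n = 4) with PP2. Together they held 46.5% ± 2.25 (SD, n = 4) of the viral sum with PP1 and 43.6% ± 0.287 (SD, n = 4) with PP2, a difference in this share that did not pass the exact permutation test (p = 0.143, two-sided). With PP1 the share was lowest in PP1 ILTV replicate 1, whose viral sum was 131410 FPKM, against 112391 to 116842 FPKM in the rest of the group. The share was not tested without this library. Relative to the viral median of each library, the PP2 minus PP1 difference of coding sequences 13 and 14 lay below that of the typical sequence, at -0.23 ± 0.07 and -0.25 ± 0.07 (SE, log2; limma adjusted p 0.00544 and 0.00248). All 73 viral coding sequences that passed the filter rose with infection under both inhibitors in the limma fit. Their median log2 change was 8.25 with PP1 and 9.41 with PP2. Coding sequences 65, 66, 67, 77, 78 and 79 did not pass the filter, with at most 0.617 FPKM in any infected library, while every tested sequence reached at least 14.5 FPKM in all 8. Their low values do not show absent transcription, as the handling of reads that match several places was not examined.

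**Figure D1:**
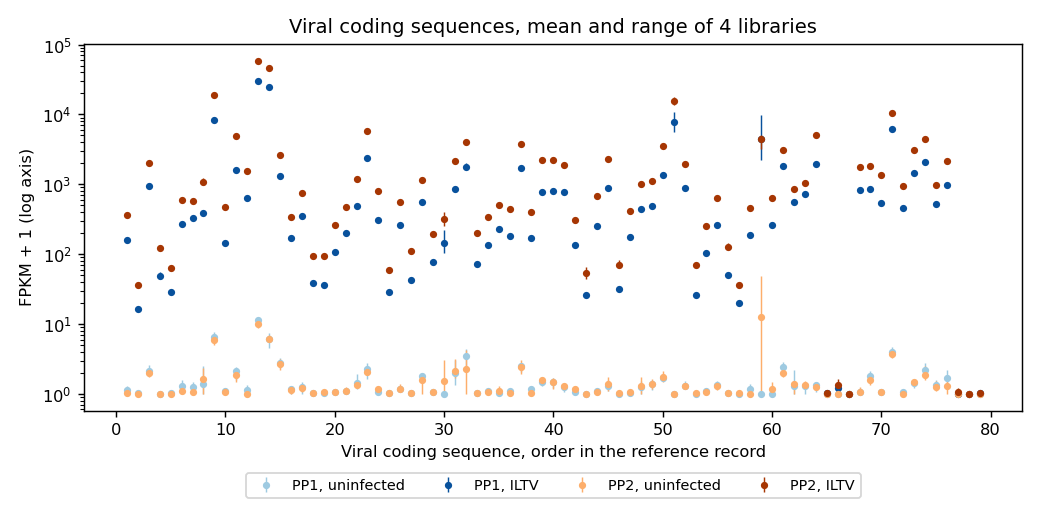
Mean FPKM + 1 on a log axis for the 79 viral coding sequences in the order of the reference record, with bars from the lowest to the highest of 4 libraries, for the 4 groups. PP2 ILTV values lie above PP1 ILTV values for nearly all sequences, both far above the uninfected groups, and sequences 65 to 67 and 77 to 79 stay near 0 FPKM.

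Viral transcripts were higher with PP2 than with PP1 in infected cells. The viral median of a library was 9.75 ± 0.08 (SD, n = 4) on the log2 scale with PP2 and 8.59 ± 0.10 (SD, n = 4) with PP1, a ratio of 2.23 (exact permutation test, two-sided, p = 0.0286, the smallest that 4 against 4 libraries allow). In the limma fit 72 of 73 coding sequences were higher with PP2, with a median log2 difference of 1.18 over all 73. The exception was coding sequence 59, at 4502 ± 3584 FPKM with PP1 and 4500 ± 872 FPKM (SD, n = 4 each) with PP2, where adjusted p was 0.877. The PP1 mean rested on replicate 1, at 9833 FPKM, and was 2725 ± 568 FPKM (SD, n = 3) without it, where the log2 difference was 0.72 ± 1.12 (SE, limma adjusted p 0.662). With all libraries its difference of 0.25 ± 1.04 (SE, log2) is too imprecise to compare with the others. This SE shares the spread of all 4 groups, among them PP2 uninfected cells, at 11.7 ± 23.5 FPKM (SD, n = 4). Relative to the viral median, in the fit over infected libraries only, coding sequence 59 lay at -0.90 ± 0.49 (SE, log2; limma adjusted p 0.198). The ranking of coding sequences was nearly the same under both inhibitors (Spearman rho 0.992 across sequences, which are not independent replicates). The 2 compounds were not measured at a matched dose, so the difference holds for PP2 at 20 µM against PP1 at 2 µM.

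The size of the difference varied along the viral record. After each library was centred on its viral median, 18 coding sequences lay above the common difference and 10 below it at an adjusted p under 0.05 in limma, and 45 did not pass. Coding sequence 10 rose from 144 ± 5.16 FPKM with PP1 to 466 ± 27.8 FPKM with PP2 (SD, n = 4 each), a ratio of 3.24. Coding sequence 11 had a ratio of 3.08 and coding sequence 39 a ratio of 2.92. The lowest ratios past the test were 1.45 for coding sequence 63, 1.54 for coding sequence 62 and 1.66 for coding sequence 71. Coding sequence 63 stood at 721 ± 9.79 FPKM with PP1 and 1043 ± 24.4 FPKM with PP2 (SD, n = 4 each). Coding sequence 9 was close to the median, with a ratio of 2.29. These sequences were chosen after their values were seen, as the highest and those farthest from the median difference.

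**Figure D2:**
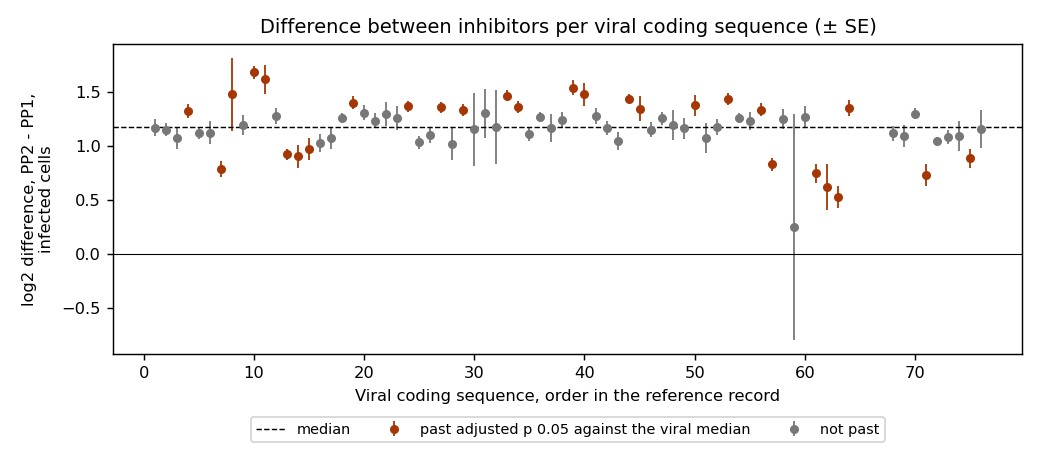
Log2 difference between PP2 and PP1 in infected cells for 73 viral coding sequences in the order of the reference record, with bars of 1 SE from limma. The dashed line marks the median of 1.18, and coloured points differ from the viral median at an adjusted p under 0.05, among them sequences 10 and 11 above it and 62 and 63 below it.

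Infection of PP1-treated cells changed 5411 of 10541 host features, 2683 upward and 2728 downward, at an adjusted p under 0.05 in limma. Most changes were small, and 214 features rose and 136 fell by at least 1 on the log2 scale. ENSGALG00000017059 rose from 0.181 ± 0.120 to 18.4 ± 2.37 FPKM (SD, n = 4 each), a log2 change of 4.04 ± 0.12 (SE). With a pseudocount of 0.1 in place of 1 this change was 6.14, as its uninfected values lay under 1 FPKM. ENSGALG00000012520 rose from 1.02 ± 0.187 to 16.4 ± 1.79 FPKM (SD, n = 4 each). ENSGALG00000009266 fell from 27.3 ± 1.43 to 2.56 ± 0.525 FPKM and ENSGALG00000008608 from 81.6 ± 1.85 to 11.4 ± 0.376 FPKM (SD, n = 4 each). Of the calls, 49.6% were upward, against 36.7% after quantile normalization.

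Infection of PP2-treated cells changed 6046 of 10541 host features, 2763 upward and 3283 downward, of which 276 rose and 135 fell by at least 1 on the log2 scale. Upward calls were 45.7% of the total, against 36.5% after quantile normalization. ENSGALG00000017059 rose again, from 0.423 ± 0.285 to 34.7 ± 1.37 FPKM (SD, n = 4 each), and ENSGALG00000008608 fell from 78.2 ± 0.879 to 8.50 ± 1.37 FPKM (SD, n = 4 each). ENSGALG00000011986 fell from 27.8 ± 3.91 to 1.69 ± 0.336 FPKM (SD, n = 4 each). ENSGALG00000028120 rose from 8.69 ± 9.73 to 112 ± 38.6 FPKM (SD, n = 4 each), a log2 change of 3.91 ± 0.51 (SE) with a limma adjusted p of 2.3e-05. The uninfected mean rested on PP2 uninfected replicate 1, at 23.3 FPKM, and without it the mean was 3.83 ± 0.294 FPKM (SD, n = 3) and the log2 change 4.49.

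Of 10541 host features, 4070 passed the infection test under both inhibitors, and 94.7% of these changed in the same direction. Across all 10541 host features the log2 changes correlated with Pearson r 0.730 and Spearman rho 0.718, where features are not independent replicates and the 2 comparisons share no library. Of features called in both, 1849 rose in both, against 703 for independent lists, 2005 fell in both, against 850, and 216 moved in opposite directions, against 1551. The Pearson r was 0.767 without ENSGALG00000026592, which is listed at 0 in all 4 PP2 uninfected libraries and at 742223 to 1180000 FPKM in the PP2 ILTV libraries.

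The difference between inhibitors in the response to infection passed an adjusted p of 0.05 for 2147 host features, where the log2 response with PP2 minus that with PP1 was above 0 for 1022 and below 0 for 1125. The sign does not give the direction of either response, since a smaller rise with PP2 also counts as below 0. Differences above 0 made up 47.6% of the calls, 51.3% under upper-quartile scaling and 53.9% after centring on the host median, an alternative chosen after seeing the data, so neither sign clearly prevailed. ENSGALG00000012357 rose with infection by 0.78 ± 0.07 (SE, log2) with PP1 and by 3.15 ± 0.07 (SE, log2) with PP2. It started lower in PP2 uninfected cells, at 3.13 ± 0.302 FPKM, than in PP1 uninfected cells, at 10.9 ± 0.672 FPKM (SD, n = 4 each). ENSGALG00000027874 rose from 38.1 ± 1.49 to 250.5 ± 4.36 FPKM with PP1 and from 43.0 ± 1.71 to 70.6 ± 3.41 FPKM with PP2 (SD, n = 4 each). ENSGALG00000028120, at 39.9 ± 16.1 and 122 ± 35.2 FPKM with PP1 (SD, n = 4 each), passed with a limma adjusted p of 0.0401. Leaving out each library gave it an adjusted p of 0.000846 to 0.0781, with differences of 2.06 to 2.86 on the log2 scale, and the call was lost in 11 of 16 such fits, all but those without PP1 uninfected replicates 2 and 3, PP1 ILTV replicate 1, PP2 uninfected replicate 1 or PP2 ILTV replicate 3. ENSGALG00000028774, at 121977 ± 92328 FPKM in PP1 ILTV and 47566 ± 15500 FPKM in PP2 ILTV cells (SD, n = 4 each), passed with a limma adjusted p of 0.0348. It started at 39756 ± 4690 FPKM in PP1 uninfected and 71518 ± 16009 FPKM in PP2 uninfected cells (SD, n = 4 each). Its response was 1.35 with PP1 (log2, limma adjusted p 0.0182), and that with PP2, at -0.63, did not pass (limma adjusted p 0.222). PP1 ILTV replicate 1 stood at 255089 FPKM, against 55220 to 113262 FPKM in the other 3 libraries, and without it the difference went from -1.98 to -1.53 on the log2 scale. Its adjusted p was 0.0174 to 0.0652 when a library was left out, and the call was lost in 9 of 16 fits, those without any 1 library of PP1 uninfected, PP1 ILTV replicate 3, PP2 uninfected replicates 1, 2 and 4 or PP2 ILTV replicate 3. Of the 2147 features, 769 changed the same way under both inhibitors, 520 of them more with PP2 and 249 more with PP1, and 216 changed in opposite directions. A further 461 passed the infection test with PP1 only, 681 with PP2 only and 20 with neither. Of the 73 viral coding sequences, 69 had a larger response with PP2 at this threshold, and the other 4 did not pass.

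**Figure D3:**
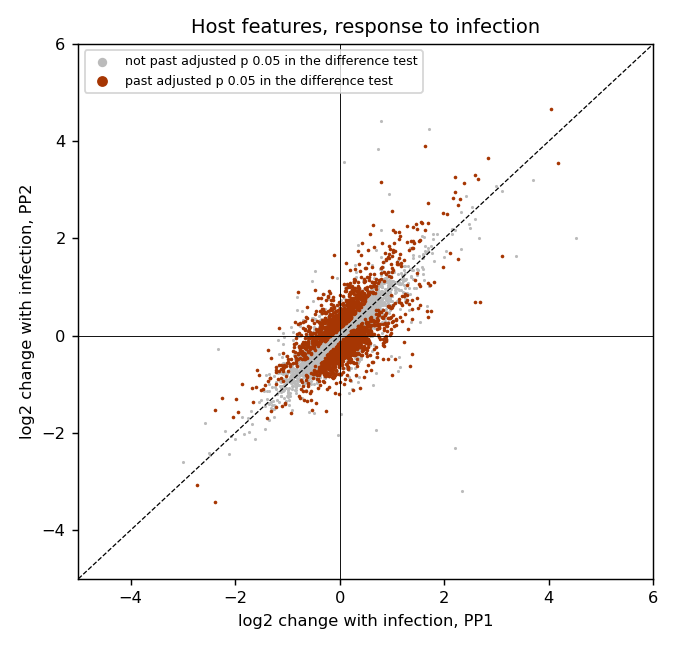
Log2 change with infection in PP1-treated cells against that in PP2-treated cells for 10541 host features, with the dashed line of equal change. Coloured points are the 2147 features past an adjusted p of 0.05 in the test of the difference, and 1 feature, ENSGALG00000026592, lies outside the plotted range of -5 to 6.

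Uninfected cells differed between the inhibitors in 2621 of 10541 host features, 1281 higher with PP2 and 1340 lower, of which 31 and 75 differed by at least 1 on the log2 scale. ENSGALG00000025721 stood at 4.61 ± 0.388 FPKM with PP1 and 40.1 ± 1.30 FPKM with PP2, and ENSGALG00000026793 at 5.55 ± 0.293 and 44.1 ± 1.47 FPKM (SD, n = 4 each). ENSGALG00000001442 was lower with PP2, at 0.814 ± 0.156 against 9.52 ± 0.591 FPKM, and so was ENSGALG00000015918, at 2.45 ± 0.584 against 18.4 ± 2.10 FPKM (SD, n = 4 each).

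Infected cells differed between the inhibitors in 3918 of 10541 host features, 1851 higher with PP2 and 2067 lower, of which 30 and 63 differed by at least 1 on the log2 scale. The same 4 identifiers led this comparison. ENSGALG00000026793 was higher with PP2 by 3.06 ± 0.07 (SE, log2) and ENSGALG00000025721 by 2.95 ± 0.13 (SE, log2). ENSGALG00000001442 was at 1.31 ± 0.426 against 8.65 ± 0.190 FPKM and ENSGALG00000015918 at 3.44 ± 0.374 against 14.9 ± 0.895 FPKM (SD, n = 4 each). With infection, ENSGALG00000026793 changed by -0.95 with PP1 and -0.68 with PP2, and ENSGALG00000025721 by -0.91 and -0.84 (log2). For ENSGALG00000001442 these changes were -0.12, which did not pass (limma adjusted p 0.341), and 0.33, and for ENSGALG00000015918 they were -0.28 and 0.37. The inhibitor differences of uninfected and infected cells correlated at Pearson r 0.354 and Spearman rho 0.344 across host features, and at Pearson r 0.412 without ENSGALG00000026592. Of features called in both states, 567 were higher with PP2 in both, against 225 for independent lists, 701 were lower in both, against 263, and 247 went in opposite directions, against 486.

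**Figure D4:**
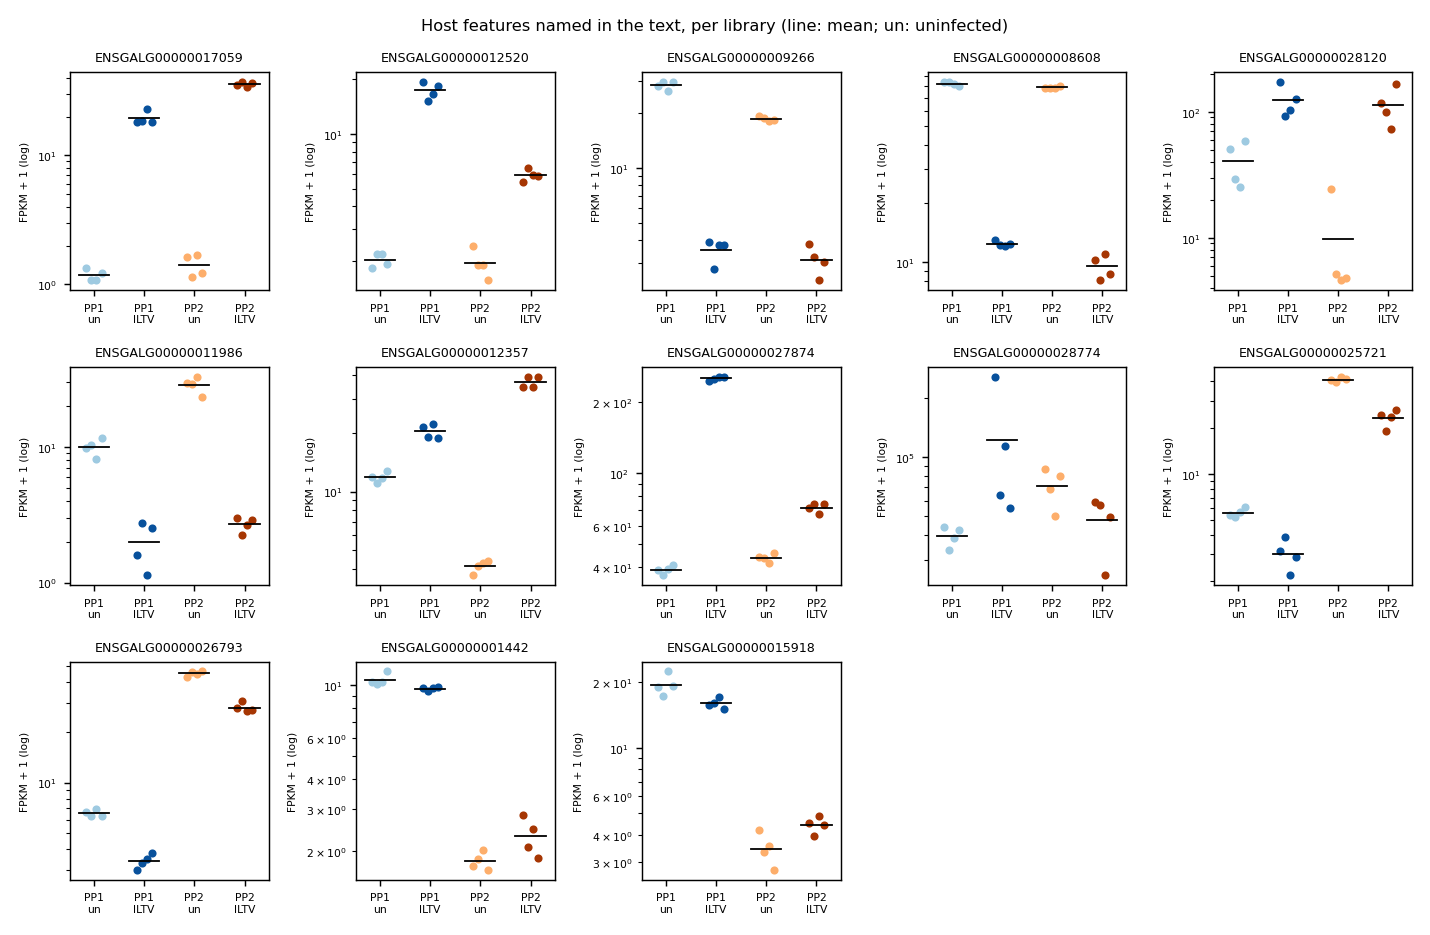
FPKM + 1 on log axes for the 13 host features named by the rule, with 1 point per library and a line at the mean of each group of 4. ENSGALG00000017059 rises and ENSGALG00000008608 falls with infection under both inhibitors, while ENSGALG00000026793 and ENSGALG00000001442 differ between the inhibitors in both infection states. ENSGALG00000026793 also falls with infection under both inhibitors.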

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

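The tests of PP1 ILTV replicate 1, of the viral values in uninfected libraries, of the dose and of host transcripts per cell were chosen only after the results were seen. Those of scaling and of other splits of the libraries were chosen before, except for the scaling by centring on the host median, which was added after seeing the data. Of 98 groups of 4 values examined for a library far from the other 3, 11 passed, where chance gives about 5%.

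Viral RNA stood higher with PP2 than with PP1 in infected cells, and 69 viral coding sequences had a larger response to infection with PP2 in the test of the difference. These are nearly the same result, as the median viral log2 difference between inhibitors was -0.00686 in uninfected cells. The median difference of responses was 1.22, against 1.18 for the difference in infected cells. Under 3 other scalings the lowest median log2 difference in infected cells was 1.09. The SD of the viral median between libraries of a group, pooled over both groups, was 0.0898. These scalings align libraries on features that are only or mostly host, whose median difference was already -0.0102, so they could move viral values little. They show that viral values were higher relative to the host majority, and cannot decide on scaling beyond that. A dose 10 times higher for PP2 cannot be told apart from the compound, because the groups were not measured at a matched dose. Fewer host transcripts per cell with PP2 would raise viral values too. The median host difference of -0.0102 cannot decide this, as values scaled to the host majority stay near 0 either way. Whether the deposited values were scaled so is not known. Median host changes with infection were also near 0, at -0.00697 with PP1 and -0.0351 with PP2 on the log2 scale, although the viral sums rose. A biological difference between the compounds stays open and untested.

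PP1 ILTV replicate 1 stood high on the features with the highest values, and its highest FPKM was 16500000, against 2290000 to 4300000 in the other 3 libraries, for ENSGALG00000021717. It was also far from the other 3 libraries for viral coding sequences 10, at 152 against 141 to 142 FPKM, 11, at 1716 against 1565 to 1589 FPKM, 13, at 30951 against 29919 to 30026 FPKM, and 59, at 9833 against 2245 to 3353 FPKM. A candidate explanation is the length correction in FPKM. Over the 16 libraries the deviation on the 20 highest host features went with how much more a read was worth in short than in long features (Pearson r 0.845, permutation p = 0.00016; Spearman rho 0.603, permutation p = 0.0154), and r was 0.644 without the 2 libraries farthest out. The permutation tests included PP1 ILTV replicate 1, which had prompted them. In this library the trend, measured on low features, was 0.0204 on the log2 scale, against a deviation of 0.588 on the 20 highest features. Whether so small a trend could account for the size of the deviation was not tested. A different depth is argued against, since this library lay -2.13% from the mean relative depth of the other 3, and no biological explanation was tested.

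Viral values above 0 in the uninfected libraries summed to 0.0411% of the infected sum with PP1 and 0.0228% with PP2. Carry-over in proportion to the infected libraries is argued against by an F of 8.81 between the rates of the 20 highest stable coding sequences, relative to their spread over the 8 uninfected libraries, and the ratio of coding sequence 14 to 13 was 0.334 to 0.657 in uninfected and 0.795 to 0.835 in infected libraries. The number 20 and the bounds of this test were set after F had been seen for the 10, 20 and 30 highest sequences, 8.32 to 11.4 over both infected profiles, so no bound was fixed in advance. It replaced a test on whole reads of 32 coding sequences, with a dispersion of 6.27 against the PP1 profile, which was dropped because whole reads are recovered more easily where uninfected reads are few. Viral RNA of another profile in these cultures stays open and cannot be told apart from carry-over from another source. The ratios of uninfected to infected value in PP1 and PP2 uninfected cells had a Spearman rho of 0.498 across 64 coding sequences. Both ratios were divided by the same PP1 ILTV means, which by itself makes them correlate, so this rho cannot decide.

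Other libraries far from their group were PP2 uninfected replicate 3 for the viral median, at 0.235 against 0.153 to 0.161 on the log2 scale, and PP2 ILTV replicate 4 for viral coding sequence 11, at 5145 against 4865 to 4900 FPKM. ENSGALG00000017059 was at 22.0 FPKM in PP1 ILTV replicate 3 against 17.1 to 17.5, and ENSGALG00000009266 at 1.78 FPKM in PP1 ILTV replicate 2 against 2.75 to 2.94. ENSGALG00000028120 was at 23.3 FPKM in PP2 uninfected replicate 1 against 3.58 to 4.15, and ENSGALG00000001442 at 10.4 FPKM in PP1 uninfected replicate 4 against 9.11 to 9.29.

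The response to infection differed between the inhibitors, by the limma test of the difference, for 10 of the 13 named host features. This count is partly set by selection, as 4 of the 13 were named because they passed this test and the others as extremes of other comparisons, while 2147 of all 10541 host features, 20.4%, passed it. On the log2 scale the response with PP2 minus that with PP1 was 0.63 for ENSGALG00000017059, -1.48 for ENSGALG00000012520, -0.33 for ENSGALG00000008608, -1.03 for ENSGALG00000011986, 0.45 for ENSGALG00000001442 and 0.65 for ENSGALG00000015918. It was 2.28 for ENSGALG00000028120, 2.37 for ENSGALG00000012357, -1.98 for ENSGALG00000027874 and -1.98 for ENSGALG00000028774. With a pseudocount of 0.1, ENSGALG00000017059 was at 0.11 (limma adjusted p 0.911) and ENSGALG00000011986 at -0.56 (adjusted p 0.623), so these 2 calls depend on the pseudocount, while ENSGALG00000026793 went from 0.27 (adjusted p 0.0514) to 0.49 (adjusted p 0.00648). The other 8 calls passed with either pseudocount.

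Other splits of the same libraries did not reach the real counts of host features. The real split was the only 1 of 35 to reach 5411 for infection with PP1, where the highest other split called 1, and the only 1 of 35 to reach 6046 for infection with PP2, where the highest other called 1. For PP2 against PP1 the real split was the only 1 of 35 in uninfected cells, 2621 against 0, and the only 1 of 35 in infected cells, 3918 against 3. For the difference of responses it was the only 1 of 100 splits drawn, 2147 against 1002. These shares cannot decide on chance. The other splits mix libraries of different groups, which puts the real difference into the spread and lowers their counts. For the difference of responses, inhibitor labels were shuffled within each infection state, which also mixes the differences between inhibitors. A share of 1 in 35 was the smallest that 35 splits allow.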

How the results depend on the processing

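Host counts stayed within 1.5 times of the reported ones under all alternatives but the fold threshold. With only the groups compared, infection changed 5327 features with PP1 and 5647 with PP2. The inhibitors then differed in 2954 features in uninfected and 3102 in infected cells, against the reported 2621 and 3918. How far the reported count in infected cells exceeds that in uninfected cells therefore depends on fitting all groups together. Leaving out each library gave 4918 to 5529 for infection with PP1, 5675 to 6100 for infection with PP2, 1793 to 2188 for the difference of responses, 2208 to 2781 for the inhibitors in uninfected cells and 3446 to 3941 in infected cells. With an absolute log2 change of at least 1 these counts were 350, 411, 74, 106 and 93, which follows from the threshold itself. The correlation of the infection responses was 0.720 to 0.733 and that of the inhibitor differences 0.338 to 0.361 when a library was left out. The latter was 0.297 with the stricter filter, and the cause was not tested. Chosen after seeing the data, features above 0 in every library gave 0.790 and 0.463, and leaving out ENSGALG00000026592, listed at 0 in all PP2 uninfected libraries, gave 0.767 and 0.412. The number of viral coding sequences higher with PP2 was 71 to 72, and that of sequences risen with infection 73 to 73 under either inhibitor, when a library was left out. The first count was 61 with a pseudocount of 0.1 and 62 with an absolute log2 change of at least 1. With the pseudocount of 0.1 the median viral difference was 1.20, against 1.18 in the main fit, so calls were lost without a smaller median difference. All 3 counts were 32 among features above 0 in every library, since fewer sequences were tested. The median viral difference was 1.17 to 1.23 when a library was left out and 1.09 after quantile normalization, with the cause not tested. Of 534 refits of host features in the comparisons that named them, 513 kept the direction and side of the threshold, 21 lost the call and 0 turned. All 21 were for the difference of responses, 11 for ENSGALG00000028120 and 10 for ENSGALG00000028774, the latter also without the 3 libraries of the steepest length trend, an alternative added after seeing the data, where its difference went from -1.98 to -1.15 (adjusted p 0.0517) and that of ENSGALG00000028120 from 2.28 to 3.23 (adjusted p 0.000438). The share of differences of responses above 0 was 44.7% to 51.6% when a library was left out and 57.3% without these 3. With the replicate block, the counts were 5428, 6079, 2119, 2609 and 3907. The replicate numbers share only a number: same-number libraries of different groups correlated at -0.228 to 0.152 after removal of group means, and 2 of 16 libraries correlated best with their own number. Count-based tests, voom weights and gene-list alternatives were not run, as the files hold FPKM without gene symbols. Whole reads were recovered for 912 low features, none of them named here, and depth is otherwise known only in relative terms, so no count interval is given.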

Other observations

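The tests of a larger response and of neighbouring coding sequences were chosen only after the results were seen, and the differences of the coding sequences had been viewed in the order of the record before the latter was written.

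Few host features went from under 1 FPKM to over 5 FPKM with infection. With PP1, 6 features were under 1 FPKM in all 4 uninfected libraries and over 5 FPKM in all 4 infected libraries, with PP2 there were 10, and 4 were shared. The 10 with PP2 include ENSGALG00000026592, listed at 0 in all PP2 uninfected libraries and at 742223 to 1180000 FPKM in the PP2 ILTV libraries. In the other direction there were 0 with PP1 and 0 with PP2. ENSGALG00000026592 and ENSGALG00000021717, singled out after their values were seen, exceeded 1000000 FPKM in at least 1 library. ENSGALG00000026592 ran from 210778 to 4750000 FPKM in the PP1 ILTV libraries.

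A hypothesis from the fold changes is a single response to infection that is larger with PP2 in every feature, as viral RNA is higher. Of the 2147 features past the test of the difference, 216 changed in opposite directions and 249 changed the same way but more with PP1. These 465 exceed the 107 false calls that the threshold allows, and so did the counts of 487 to 496 under 3 other scalings, which argues against it as the whole account. Of all 4070 features called under both inhibitors, 5.31% went in opposite directions. A share of 21.9%, over features past all 3 tests, was used first and dropped, because choosing features by the test of the difference raises it. Of the 216 features, 92 rose with PP2 and 124 fell with PP2.

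A second hypothesis is that neighbouring viral coding sequences share their difference between inhibitors. Over 71 neighbouring pairs the centred differences correlated at r 0.190, just above the 95th percentile of random orders, 0.181 (permutation test, one-sided, p = 0.0428), which may reflect a weak tendency of this kind but is not independent of the values that prompted the test.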
